A study of Rattus norvegicus with 6 samples.

How the data were processed

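Liver RNA of male Sprague Dawley rats was measured on Affymetrix Rat Genome U34A arrays, 1 array per sample, in 2 diet groups of 3 samples each, and the arrays were taken as the replicates. Both groups received liquid diets by total enteral nutrition for 3 weeks. The Control diet held 5% corn oil and gave 187 kcal per kg of metabolic body mass per day, and the NASH diet held 70% corn oil and gave 220 kcal on the same basis. The tissue and the array type are given per the file headers of the instrument records. The groups were taken from the sample titles, because the free-text description of every sample carries the wording of the first Control sample. Nothing in the sources used here states that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

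The deposited values are linear MAS5 intensities, 1 signal per probe set and array, per the submitters' processing notes, which name MAS5 without a version. MAS5 subtracts background and combines the perfect-match and mismatch probes of a set into 1 signal. The scaling target and the background settings are not given in the sources used here, and no detection calls were used. The instrument records hold other information only (array type, tissue, and wash and scan settings, per the file headers) and no expression values. The deposited table was checked for a common scale and held none, with trimmed mean signals (2% trimmed) between 73.6 and 117 over the 6 arrays. The plan had assumed scaled signals. Because the table was not normalized between arrays, the arrays were quantile normalized before any test, and the table as deposited, the scaling first planned, became an alternative. This exchange was made after the table was seen.

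Quantile-normalized signals were set on the log2 scale after an offset of 2.21 was added, the 10th percentile of all values, so that fold changes are on the log2(signal + offset) scale and understate the change of dim probe sets. Of 8799 probe sets, 59 array controls were left out, and those of the remaining 8740 whose mean log2 over the 6 arrays lay above the 40th percentile (3.92) were tested, 5244 in all. Gene symbols came from the platform's annotation table. It gave 1 symbol for 7006 probe sets (4736 distinct symbols) and several for 308, none of which is named here, while 1426 were not in the annotation and are unnamed here. No symbol was altered by the reference gene table. No genome was used, and coordinates are not given. Where several probe sets measured a gene, the list tests used the one with the highest mean log2, and the text says where others disagree.

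NASH and Control were compared with limma (lmFit and eBayes with an intensity trend, 4 residual and 3.90 prior degrees of freedom) without covariates, and probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called. Of 35 gene lists, 34 with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, again at an adjusted p under 0.05 over the lists. The list of neutrophil genes had no member above the filter and was not tested. The lists covered fatty acid, cholesterol, bile acid, glucose and lipoprotein metabolism, cytochromes P450, stress responses, inflammation, fibrosis and the cell types a liver sample can hold. Each list was also tested with a correlation estimated from the data and with fry. Quality measures per array were compared between groups with an exact permutation test, two-sided, for which 0.1 is the smallest p that 3 against 3 arrays allow.

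Genes were named by a rule with 3 parts. The first takes the 10 largest rises and falls past the threshold without overlap between groups or, with fewer than 5 in a direction, the 10 with the smallest p in that direction. The second takes up to 4 members of each list with the smallest p. The third is a fixed set of liver genes (Cyp2e1, Cyp4a1, Cpt1a, Cd36, Fasn, Scd, Srebf1, Acaca, Cyp7a1, Tnf, Il1b, Ccl2, Tgfb1, Col1a1, Timp1, Hmox1, Gsta2, Ppara, Pparg, Alb and Gapdh), of which some members are not reported here. The design, the lists, the naming rule and all but 2 of the alternatives were written before the data were examined, except that the scaling used for the tests was chosen after the table was seen, from among the settings already listed. The alternatives covered scaling, offset, filter, variance prior, array weights, the replicate number and the wash record as blocks, the choice of probe set, thresholds, and each array left out in turn. Fits without both Control 2 and NASH 2, and on the arrays with a filled wash record only, were added after seeing the data.

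The test was run on simulated data built from these arrays, with 200 of 5244 probe sets shifted in each of 20 simulations. It called 37.6% of probe sets shifted by 2-fold, 77.8% at 2.83-fold, 92.9% at 4-fold and 99.4% at 8-fold, with 5.52% false among the calls and 0 with the wrong sign. Noise was simulated as normal and independent, with the moderated variances and no array that stood apart. The adjusted threshold is also easier to pass with 200 shifted probe sets than with few. These shares may therefore be too high for the real arrays. A list shifted by 0.5 on the log2 scale, with members simulated as independent, was called in 20 of 20 simulations with the preset correlation, in 9 with an estimated correlation and in 11 by fry. Correlations estimated from these data reached 0.72 (cholesterol synthesis), so these counts do not show how the preset test behaves with correlated members. The number of arrays limits the precision of every value. Calculations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.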

Results

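Liver RNA was measured in 6 samples, 3 from Control rats on a 5% corn oil liquid diet and 3 from rats on the NASH diet, named for nonalcoholic steatohepatitis, with 70% corn oil and a higher energy supply. Corn oil is rich in polyunsaturated fat. Because fat content and energy supply differ together, the comparison is between the diets as a whole. Deposited trimmed mean signals per array lay between 73.6 and 117, and the 20 brightest probe sets held 8.17% to 9.25% of the summed signal. Correlations between arrays over log2 values lay between 0.914 and 0.954 for the 15 pairs, and no pair held duplicate values. Control 3 had the highest ratios of 3' to 5' control signal, 5.07 for actin (others 2.15 to 2.93) and 2.04 for Gapdh (others 1.08 to 1.29). Between the diets, exact permutation p-values of the quality measures (two-sided, 3 against 3) lay from 0.4 to 1.0, where 0.1 is the smallest possible. Wash records were filled for Control 1, Control 3, NASH 1 and NASH 2. The recorded hybridization time, taken here as the washing run, was earlier for the 2 Control arrays among them and later for the 2 NASH arrays. Run and diet therefore cannot be told apart among these 4, and whether the 2 NASH arrays shared 1 run was not checked. The recorded scan order mixed the groups: NASH 3, NASH 2, Control 3, Control 1, NASH 1, Control 2. The wash record of Control 2 and NASH 3 was blank.

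Both groups held an array that stood apart, NASH 2 and Control 2, and Control 3 differed from the others in some measures. In the fit with array weights, Control 2 got 0.45, Control 3 0.49 and NASH 2 0.78, against 1.46 to 2.09 for the other arrays. The genes named in this paragraph were chosen after their values were seen. NASH 2 carried transcripts typical of brown fat and of skeletal muscle. In deposited signals, the fatty acid binding protein Fabp4 reached 1044 against at most 4.47 in the other arrays, the brown fat uncoupling protein Ucp1 1100 against at most 15.97, the skeletal muscle actin Acta1 1322 against at most 18.9, and muscle creatine kinase Ckm 447 against at most 50.6. Control 2 had the highest log2 signals of the serine dehydratase Sds (10.83 against at most 6.44) and the clock factor Dbp (7.09 against at most 3.48). It had the lowest signals of the clock factor Bmal1 (2.02 against at least 5.14), Acat2 (2.01 against at least 6.47) and the sterol enzyme Sqle (3.78 against at least 6.38). Of 8740 probe sets, 61 lay at least 4-fold above the other 5 arrays in NASH 2 and 10 in Control 2, and 14 lay at least 4-fold below them in Control 2. The corresponding numbers above the others were 2 in Control 3, 2 in NASH 3 and 0 in Control 1 and NASH 1, and those below were 11 in Control 3, 2 in Control 1, 2 in NASH 2 and 0 in NASH 1 and NASH 3.

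**Figure D1:**
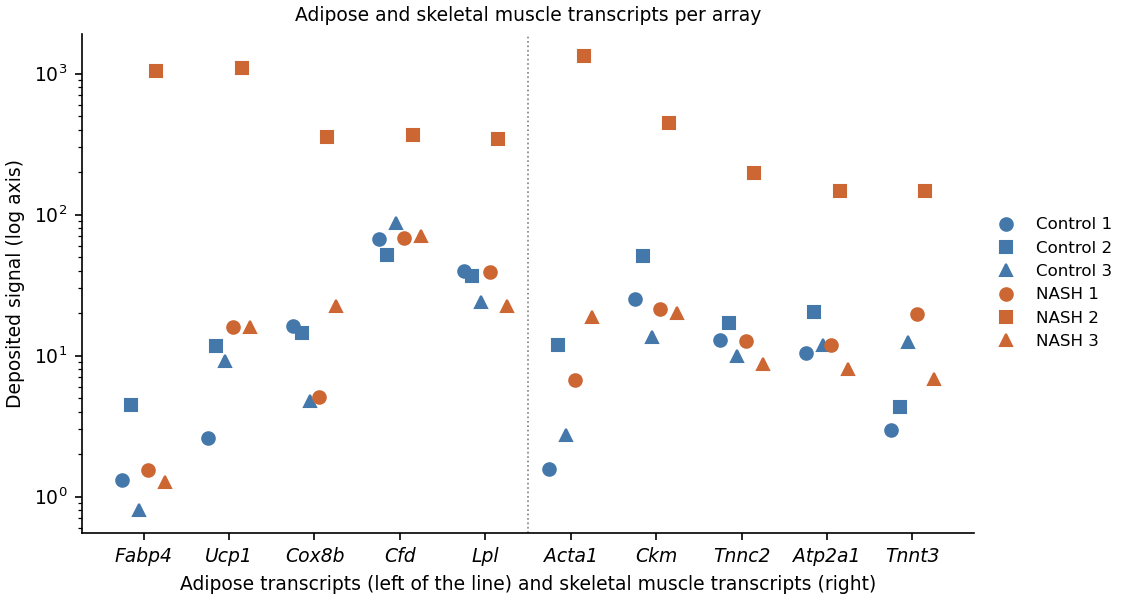
Deposited signal (log axis) of 5 adipose transcripts and 5 skeletal muscle transcripts, 1 point per array. NASH 2 lies above the other 5 arrays for each, with a Fabp4 signal of 1044 where the highest other array reached 4.47.

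**Figure D2:**
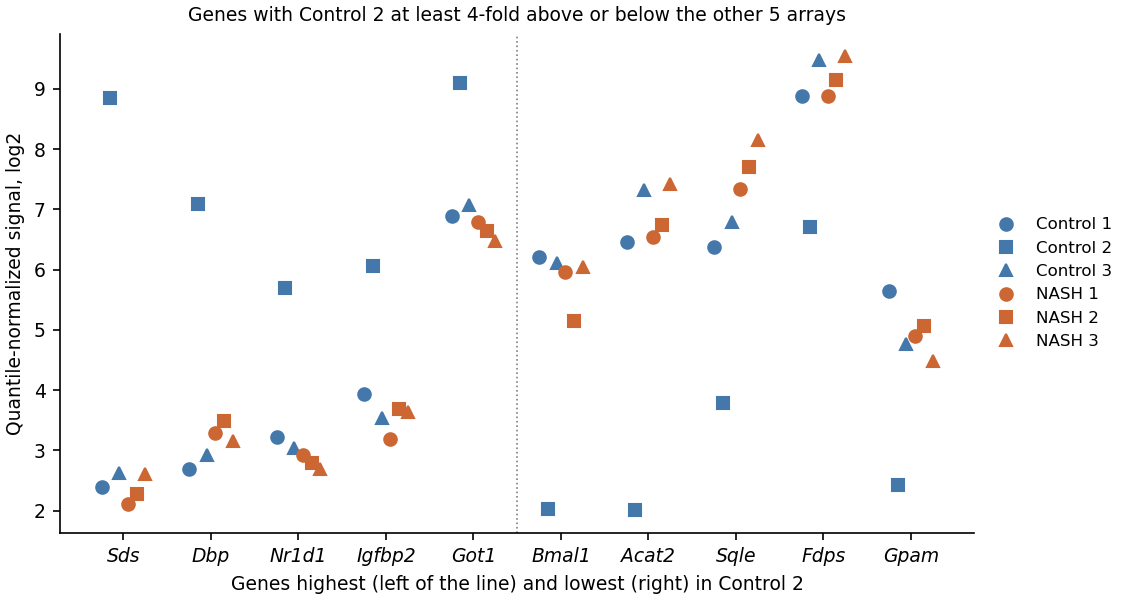
Quantile-normalized log2 signal of 10 genes in which Control 2 stood at least 4-fold above or below the other 5 arrays, 1 point per array, Sds by the probe set with the widest gap. Dbp reached 7.09 in Control 2 against at most 3.48 elsewhere, and Bmal1 2.02 against at least 5.14.

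The comparison of NASH with Control asks which liver transcripts differed in a rat model of steatohepatitis on a high polyunsaturated fat diet. Acot2 and Eci1, enzymes of mitochondrial fatty acid metabolism, and the transporter Cd36 rose in NASH, and the desaturase Scd and the binding protein Igfbp1 fell. Acot2, a mitochondrial acyl-CoA thioesterase, rose by 3.25 ± 0.31 on the log2 scale (standard error, n = 3 per group), or 9.49-fold. The fatty acid transporter Cd36 rose by 2.98 ± 0.35 (7.92-fold) and Eci1, an isomerase needed to oxidize unsaturated fatty acids, rose by 2.62 ± 0.32 (6.15-fold). Scd, stearoyl-CoA desaturase, fell by 4.13 ± 0.48 on the log2 scale and was 17.5-fold lower in NASH. Igfbp1, the insulin-repressed binding protein of insulin-like growth factors, fell by 1.76 ± 0.21 on that scale and was 3.38-fold lower. These were the named genes among 7 probe sets called of 5244, 5 higher and 2 lower, by limma at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values were 0.0224 for Acot2, 0.0341 for Cd36, Scd and Igfbp1, and 0.0361 for Eci1. The other calls, AF072411_at (2.35, adjusted p = 0.0224) and AF072411_g_at (2.07, adjusted p = 0.0480), carry several gene symbols each and are not named. For each of the 7, the 3 values of NASH lay apart from the 3 of Control.

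A second Scd probe set had a difference of −4.84 (limma adjusted p = 0.0589) and a second Cd36 probe set one of 1.64 (adjusted p = 0.141). The called Cd36 probe set was close to the floor in Control livers, with deposited signals of 1.71 to 4.98 against 23.1 to 58.8 in NASH, so its fold depends on the offset. Of the other Eci1 probe sets, D00729_g_at had a difference of 2.13 (adjusted p = 0.164) and rc_AA799541_at one of −0.19. A second Acot2 probe set, AB010429_s_at, had a smaller difference of 1.07 ± 0.34 (2.1-fold) and did not pass the threshold. The size of the Acot2 rise therefore depends on the probe set. Acot2 and Acot1 are close paralogs that probes may share. None of the 7 calls was kept when Control 1, Control 2, Control 3, NASH 1 or NASH 3 was left out, while without NASH 2 there were 17, of which 4 were among the 7 (Acot2, Eci1, Scd and AF072411_at). With no filter on dim probe sets 0 were called by limma (lowest adjusted p 0.0552, with 630 at an unadjusted p under 0.05), and with the wash record as a block 3 were.

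**Figure D3:**
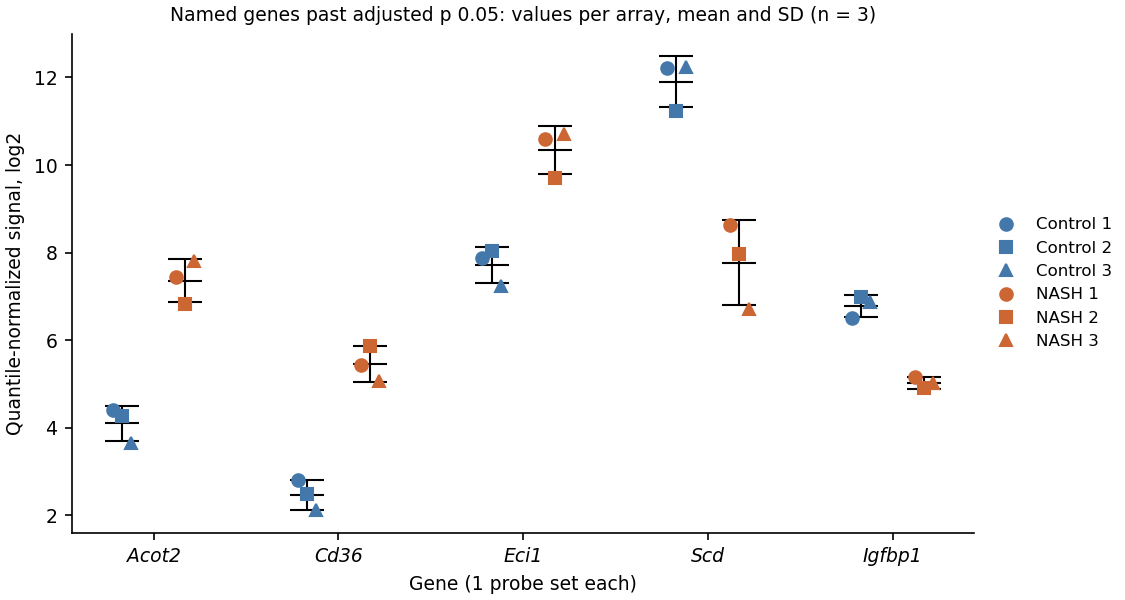
Quantile-normalized log2 signal of the 5 named genes past adjusted p 0.05, 1 point per array with the mean and SD of each group (n = 3). The groups do not overlap for any of them, and the Scd mean is 11.90 in Control and 7.77 in NASH.

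Of the 7 genes next in order on the higher side, none of which passed, 5 belong to fatty acid oxidation or sterol synthesis. Acaa2 and Acadl of mitochondrial beta-oxidation had differences of 1.07 and 1.00 (limma adjusted p = 0.0761 and 0.109), and Hadhb one of 0.93 (0.188). Idi1 and Msmo1 of cholesterol synthesis had differences of 2.65 and 1.72 (adjusted p = 0.141 and 0.198). Slfn2 differed by 1.72 (adjusted p = 0.0761) and the small heat shock protein Hspb1 by 1.87 (adjusted p = 0.158). The other 3 Hspb1 probe sets had smaller differences of 1.10, 0.77 and 0.27 (limma adjusted p from 0.462 to 0.780). On the lower side, the triokinase Tkfc had a difference of −1.70 and the phosphatase Dusp1 one of −1.32 (adjusted p = 0.0876 for both), and the apolipoprotein Apoa4 one of −2.22 (adjusted p = 0.102). Serpina4 followed at −1.13, Atp1b1 at −1.22, the liver pyruvate kinase Pklr at −1.84, the stress protein Nupr1 at −1.76 and the glucose-6-phosphate transporter Slc37a4 at −1.08, with limma adjusted p-values from 0.141 to 0.226. At an unadjusted p under 0.05 there were 412 probe sets, 200 higher and 212 lower, where 262.2 are expected by chance. Groups did not overlap for 750 probe sets, 14.3% of those tested, where chance gives 10% or 524.4.

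Liver genes fixed for naming in advance showed no call beyond Cd36 and Scd. Albumin (Alb) differed by −0.06 and Cyp2e1, a cytochrome P450 that generates reactive oxygen, by 0.23 (limma adjusted p = 0.868 and 0.738). Cyp4a1, a fatty acid omega-hydroxylase, differed by 1.70 (adjusted p = 0.398) and Cpt1a, the mitochondrial fatty acid entry step, by 0.90 (adjusted p = 0.620, and by 0.57 without Control 3 to 1.40 without Control 2). The fatty acid synthase Fasn differed by 0.15 with 1 probe set and −0.22 with another, and by −0.08 with no scaling between arrays. Acaca differed by 0.13, Srebf1 by −0.35, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 0.39, Ppara by −0.61 and Hmox1 by 0.37, none past the threshold. For inflammation and fibrosis, Il1b differed by 0.56, Ccl2 by 0.30, Col1a1 by −0.20 (with 2 of its other 3 probe sets of the opposite sign) and Timp1 by −0.35, also not past it. Many of these differences rest on single arrays. Leaving out 1 array at a time gave −0.06 (without NASH 3) to 1.12 (without NASH 1) for Cyp7a1, −0.59 to 0.79 for Fasn, −0.15 to 0.54 for Acaca, −0.96 to 0.54 for Col1a1 and 0.07 to 0.39 for Cyp2e1. Without Control 2, Il1b differed by 0.24, Ppara by −0.36 and Timp1 by −0.20, and Ccl2 differed by 0.12 without NASH 2 and 0.48 without NASH 1. Of 153 probe sets under the naming rule, 74 moved by more than 1.5 times or turned sign with 1 array left out, and 14 of them turned sign. Tnf, Tgfb1 and Pparg lay below the intensity filter, and Gsta2 and Gapdh were not analysed here.

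Genes of fatty acid oxidation were higher in NASH as a group. Of 21 measured mitochondrial fatty acid oxidation and ketogenesis genes, 19 were higher and 2 (Acsl1 and Acads) lower, with a mean difference of 0.83 on the log2 scale, or a camera adjusted p of 2.26e-13 with the preset correlation and 0.131 with an estimated one, which ended the call. The list mean lay between −0.43 and −0.40 in the 3 Control arrays and between 0.28 and 0.50 in the 3 NASH arrays. Acot2 rose over all probe sets tested, and 10 members rose when adjusted over the list alone, among them Acaa2, Acadl and Hadhb. Fry, a self-contained test, gave this list an adjusted p of 0.0207. Of 19 peroxisomal and omega-oxidation genes, 15 were higher and 4 lower (mean 0.80, camera adjusted p = 4.95e-06, adjusted p = 0.473 with an estimated correlation). Ech1 (1.66) and Cyp4a1 (1.70) rose adjusted over the list alone and none over all probe sets, with Crot at 1.41 and Acot1 at 3.40. The peroxisomal mean was −0.27 in NASH 2, against 0.61 in NASH 1 and 0.86 in NASH 3. Without NASH 2 the difference was 1.13 with 17 of 19 higher, and limma called all 3 Cyp4a1 probe sets (2.59, 2.43 and 2.23), Acot1 (4.86), Ehhadh (2.09), Ech1 (2.04), Pex11a (2.09) and Acaa2 (1.18), genes listed here after their values were seen. The differences were 0.78 for the mitochondrial and 0.60 for the peroxisomal list among the 4 arrays with a filled wash record, and 0.94 and 1.21 between NASH 3 and Control 2, whose records were blank.

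**Figure D4:**
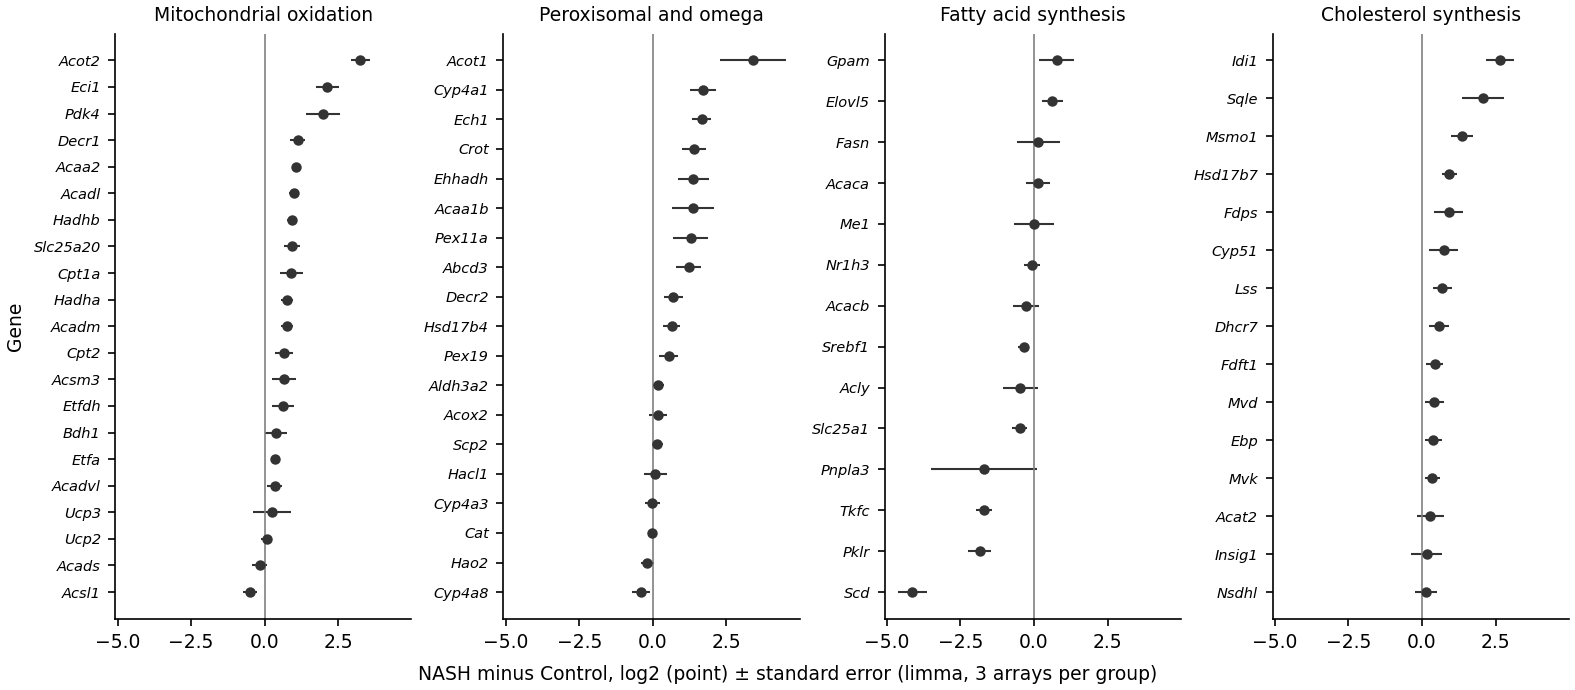
NASH minus Control on the log2 scale with its standard error (limma, 3 arrays per group) for each measured gene of 4 lists. In the mitochondrial list 19 of 21 genes lie above 0 and in the cholesterol list 15 of 15, while in the fatty acid synthesis list 10 of 14 lie below 0.

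Fatty acid synthesis genes were lower in NASH on average, led by Scd. Of 14 measured genes, 10 were lower and 4 higher, with a mean difference of −0.67 and a camera adjusted p of 0.0307, but an adjusted p = 0.714 with an estimated correlation. Scd fell over all probe sets tested, and Scd, Tkfc and Pklr fell adjusted over the list alone. Tkfc and Pklr serve fructose and glucose breakdown upstream of synthesis. Slc25a1 differed by −0.48 (−0.27 without NASH 2), and the synthesis enzymes Fasn and Acaca differed by less than their standard errors. The list mean was 0.99 in Control 1 and 0.66 in Control 3 but −0.65 in Control 2, the array with low Acat2, Sqle and Bmal1, and −0.65 to −0.17 in NASH. The difference was −0.34 without Control 1 (camera adjusted p = 0.617) and −0.50 without Control 3 (0.123), where the call ended, and −1.24 without Control 2. It was −1.004 among the arrays with a filled wash record and 0.0043 between NASH 3 and Control 2.

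Cholesterol synthesis genes were all higher in NASH. The mean difference of the 15 measured genes was 0.80, with a camera adjusted p of 6.78e-07 and an adjusted p = 0.473 with an estimated correlation. Their list was called in 18 of the 21 alternative settings, most of which kept the preset correlation, but not by fry (adjusted p = 0.376). None rose over all probe sets tested, and Idi1 (2.65), Hsd17b7 (0.92) and Msmo1 (1.37 for its brighter probe set) rose adjusted over the list alone, with Sqle at 2.07 (1.16 without Control 2). The list mean was −1.22 in Control 2, against −0.17 in Control 1 and 0.18 in Control 3, and lay between 0.12 and 0.69 in NASH. Without Control 2, in which Sqle and Acat2 stood apart, the difference was 0.40 with 12 of 15 higher (camera adjusted p = 0.00907). It was 0.25 among the 4 arrays with a filled wash record and 1.91 between NASH 3 and Control 2.

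Genes of lipid uptake, storage and droplets were also higher in NASH, 9 of 11 measured members. The mean difference was 0.74, with a camera adjusted p of 5.34e-05 and an adjusted p = 0.335 with an estimated correlation. Over all probe sets tested no probe set taken for the list passed, while Cd36 (1.64) and the droplet protein Cidea (2.17) rose and Fabp5 (−2.002) fell adjusted over the list alone, and the acyl-CoA synthetase Slc27a2 differed by 0.55. The list mean was 0.90 in NASH 2, the array with fat and muscle transcripts, against 0.12 in NASH 1 and 0.09 in NASH 3, and Cidea and Lipe are also fat cell genes. Without NASH 2 the list difference was 0.48 (camera adjusted p = 0.000199) and that of Cidea 1.43. It was 0.73 among the arrays with a filled wash record and 0.75 between those with a blank one.

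Adipose tissue markers were higher in NASH for 4 of 5 measured members (mean 0.54, camera adjusted p = 0.0376, adjusted p = 0.532 with an estimated correlation), and 0 passed adjusted over the list alone. Lipe differed by 1.13 and the adipokine Cfd by 1.06 (0.38 and 0.30 without NASH 2), Adrb3 by 0.39 and Lep by 0.21 (0.26 and 0.08 without it). The list mean was 0.93 in NASH 2 and −0.15 and 0.04 in the other NASH arrays. The call ended without NASH 2 (0.22, camera adjusted p = 0.169), without Control 1 (0.150) and without Control 3 (0.256). Lymphocyte markers were higher for 8 of 10 measured members, with 11 more below the filter, among them Cd3d, Cd3g, Cd8a and Cd2 (mean 0.38, adjusted p = 0.0243, adjusted p = 0.532 with an estimated correlation), led by Coro1a (1.47), Cd48 (0.84), Klrk1 (0.40) and Cd4 (0.36), with 0 passing adjusted over the list alone. Coro1a and Cd48 are also made by other leukocytes. Without NASH 2 Coro1a differed by 1.02 and Cd48 by 0.43, while Klrk1 differed by 0.23 without Control 3 and Cd4 by 0.20 without Control 1. The groups overlapped for Coro1a, with 4.79 in Control 3 and 4.70 in NASH 3. The lymphocyte mean was also highest in NASH 2, 0.59 against at most 0.06 elsewhere, and the call ended without NASH 2 (0.18, camera adjusted p = 0.266), Control 1 (0.0625) or Control 3 (0.0569). Hepatocyte markers were lower for 16 of 23 members (mean −0.22, adjusted p = 0.0300, adjusted p = 0.499 with an estimated correlation), with Foxa2 at −0.97, the clotting factor F10 at −0.81, Otc at −0.71 (−0.49 and −0.46 without NASH 2), Ambp at −0.27 and 0 past the threshold adjusted over the list alone. Their mean was −0.27 in NASH 2 and 0.28 in Control 2, the extremes of the 6 arrays, and the call ended without NASH 2 (−0.15, camera adjusted p = 0.0745) and without Control 2 (−0.14, 0.399). Among the arrays with filled wash records the differences were 0.76 for adipose, 0.46 for lymphocyte and −0.15 for hepatocyte markers, and between those with blank ones 0.11, 0.22 and −0.38.

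**Figure D5:**
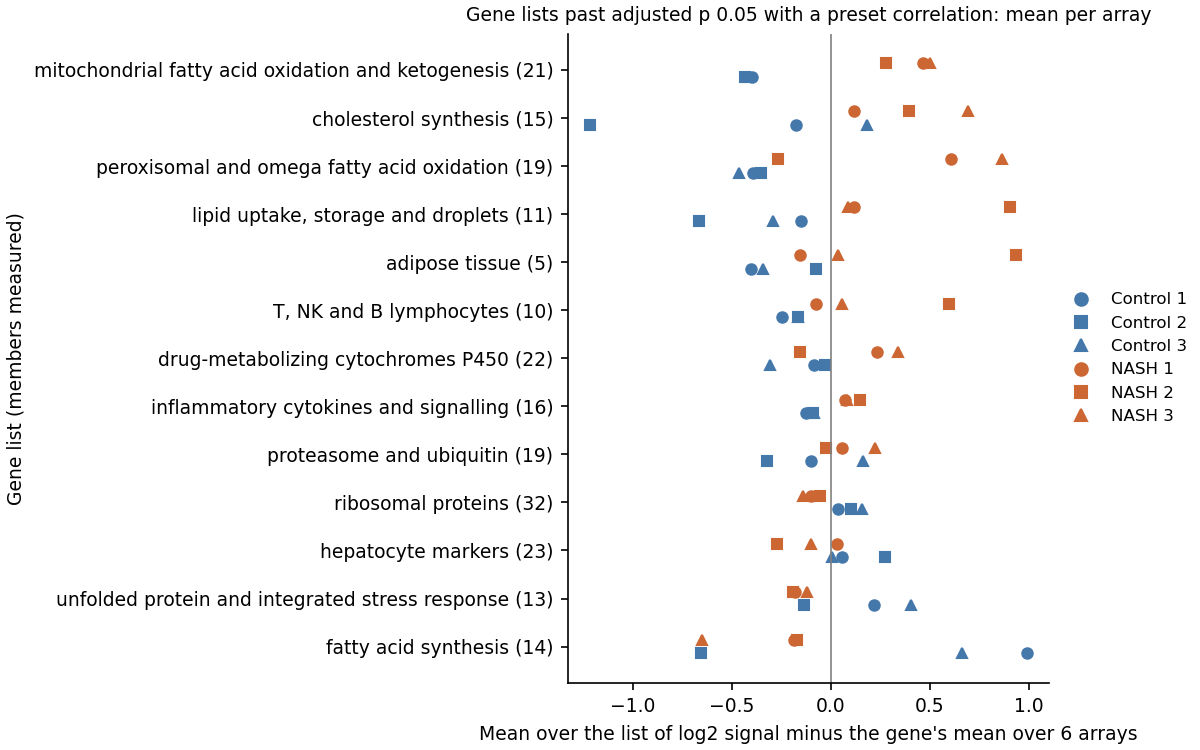
Mean of each called gene list per array, as log2 signal minus the gene's mean over the 6 arrays, with the number of measured members in parentheses. The mitochondrial oxidation list separates NASH (0.28 to 0.50) from Control (−0.43 to −0.40), while NASH 2 stands apart in the adipose (0.93) and lymphocyte (0.59) lists and Control 2 in cholesterol synthesis (−1.22).

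Drug-metabolizing cytochromes P450 were higher in NASH for 17 of 22 measured members, with a mean difference of 0.28 (camera adjusted p = 0.00246, adjusted p = 0.473 with an estimated correlation). Cyp3a9 (1.29), Cyp2a1 (0.84) and Cyp2b2 (1.46) rose adjusted over the list alone and none over all probe sets tested, and Cyp2f4 differed by −0.81. Members of this family are similar in sequence, so that probes may share transcripts. The list mean was −0.15 in NASH 2 against 0.24 and 0.34 in the other NASH arrays. The call ended without Control 3 (0.20, camera adjusted p = 0.0569), and the difference was 0.43 without NASH 2 and 0.18 without NASH 3. Within the filled and the blank wash records it was 0.24 and 0.37.

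Inflammatory cytokine and signalling genes were slightly higher in NASH, 12 of 16 measured, with 13 more below the filter. The mean difference was 0.20 (camera adjusted p = 0.0312, adjusted p = 0.473 with an estimated correlation), and 0 members passed adjusted over the list alone. Il10 differed by 0.60, Il1b by 0.56, Tnfrsf1a by 0.42 and Il1a by −0.48. Leaving out 1 array gave 0.39 (Control 3) to 0.92 (Control 2) for Il10, 0.24 (Control 2) to 0.75 for Il1b and −0.28 (NASH 2) to −0.60 for Il1a. The call ended without Control 1 (camera adjusted p = 0.124), Control 3 (0.0783) or NASH 2 (0.124), with no filter on dim probe sets (0.13, adjusted p = 0.113) and with no scaling between arrays. The fibrosis and stellate cell list was not called, 11 of 20 higher (mean 0.03, camera adjusted p = 0.949), with Pdgfra at −0.46, Mmp14 at −0.65 (−0.41 without NASH 2 and −1.03 without NASH 1) and Reln at −0.33, and its mean was −0.12 with no scaling. Its array mean was 0.47 in NASH 2 against −0.10 in NASH 1 and −0.32 in NASH 3, and without NASH 2 16 of 20 members were lower (−0.19, camera adjusted p = 0.179). The list of macrophage and Kupffer cell genes was not called (4 of 8 higher, adjusted p = 0.982, median 0.03 and mean −0.02), nor was that of class II antigen presentation (6 of 8 higher, adjusted p = 0.921, median 0.07 and mean −0.04). Class II genes had an array mean of 0.36 in NASH 2 and −0.21 in the other NASH arrays, with 1 of 8 higher without NASH 2 (−0.24, camera adjusted p = 0.266). The interferon response (4 of 7 higher, adjusted p = 0.969, median 0.05 and mean −0.01) and the acute phase (9 of 20 higher, adjusted p = 0.969) were not called either, although Stat2 was at −0.65, A2m at −0.83 and Orm1 at 0.88. Within the filled and blank wash records the inflammatory difference was 0.22 and 0.17, and that of the fibrosis list 0.25 and −0.40.

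Ribosomal protein genes were lower in NASH by a small amount, 29 of 32 measured members. The ribosomal list was called in 18 of the 21 alternative settings, most of which kept the preset correlation, but not by fry (adjusted p = 0.150). The mean difference was −0.20 (camera adjusted p = 0.00346, adjusted p = 0.473 with an estimated correlation), with Rpl3 at −0.54, Rpl22 at −0.40 (−0.25 without Control 2), Rps9 at −0.36 and Rplp0 at −0.30 and 0 passing adjusted over the list alone. All 3 NASH arrays lay below all 3 Control arrays. Genes of the unfolded protein and integrated stress response were lower for 11 of 13 members (mean −0.32, adjusted p = 0.0312, adjusted p = 0.473 with an estimated correlation). The stress kinase Eif2ak3 was at −1.01 (−0.65 without NASH 2), Trib3 at −0.50 (−0.30 without Control 2), Hsp90b1 at −0.47 (−0.22 without Control 3 and −0.73 without Control 2, with its other probe sets of the opposite sign) and Canx at −0.26, and 0 passed adjusted over the list alone. This call ended without Control 1 (camera adjusted p = 0.150), Control 3 (−0.20, 0.256) or NASH 1 (0.0841), and with no scaling between arrays. Proteasome and ubiquitin genes were higher for 15 of 19 members (mean 0.17, adjusted p = 0.0194, adjusted p = 0.714 with an estimated correlation), with Psma1 at 0.50, Psma5 at 0.45, Psmd1 at 0.37 and Psmb2 at 0.30 and 0 passing adjusted over the list alone. Their mean was −0.32 in Control 2, the lowest of the arrays, and the call ended without Control 2 (0.06, camera adjusted p = 0.397), without NASH 3 (0.10, 0.114) and with no scaling, while the difference was 0.30 without Control 3. Within the filled wash records the differences were −0.17 for ribosomal, −0.49 for stress and −0.01 for proteasome genes, and within the blank ones −0.24, 0.02 and 0.55. The median of all probe sets shifted by −0.02 with quantile normalization and by −0.17 with no scaling, against which the small differences of these lists are read.

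Genes of glucose metabolism were mixed. In gluconeogenesis 6 of 11 members were lower (mean −0.29, camera adjusted p = 0.331). The array mean of this list was highest in Control 2 (0.80), and without Control 2 6 of 11 were higher (0.12, camera adjusted p = 0.635). Igfbp1, counted in that list as an insulin-regulated gene, fell over all probe sets tested, Slc37a4 (−0.98) fell adjusted over the list alone, and Pck1, the rate-limiting enzyme, differed by 1.12 (0.68 without Control 1 and 1.83 without Control 2) and Fbp1 by −0.41 (−0.10 without NASH 2 and −0.63 without NASH 1). In glycolysis and glycogen metabolism 9 of 14 members were lower (adjusted p = 0.156). Pklr fell adjusted over the list alone, Khk differed by −0.70, Pygl by −0.87 (−0.57 without Control 3) and Pfkl by 0.77, and this list was called lower without Control 2 (−0.46, camera adjusted p = 0.00434). Apolipoprotein and lipoprotein genes were lower for 9 of 13 members (adjusted p = 0.156), with Apoa4 falling adjusted over the list alone, Apom at −1.06, Apoe at −0.20 and Scarb1 at 0.71 (0.43 without Control 2). Bile acid genes were not called (adjusted p = 0.563, mean 0.08 and median −0.05, with a mean of −0.06 with no scaling), with Cyp7b1 at 0.91 and Abcb4 at 0.89 (0.51 without Control 3). Their mean was 0.17 without Control 2, and the list was called higher without both Control 2 and NASH 2 (0.25, 12 of 16 higher, camera adjusted p = 0.0447). In the growth hormone axis (adjusted p = 0.851) the prolactin receptor Prlr rose (2.18) and Igfbp1 and Cish (−0.92) fell adjusted over the list alone.

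The remaining lists were not called in the main fit. Under the 21 alternative settings, the urea cycle list was called in 3 and that of p53 targets in 4. Urea cycle and amino acid genes were lower for 19 of 24 members (mean −0.27, camera adjusted p = 0.0797), with Got2 at −0.73 (−0.44 without NASH 2) and Ass1 at −0.66 (−0.40 without Control 2). This rested on Control 2, whose list mean was 0.64: without it 13 of 24 were lower (0.02, camera adjusted p = 0.769). Within the filled and blank wash records the difference was 0.05 and −0.91, and that of gluconeogenesis 0.13 and −1.14. Targets of p53 were higher for 6 of 7 (adjusted p = 0.0550), with Ccng1 at 0.78 (0.48 without NASH 1) and Cdkn1a at 0.51 (0.30 without Control 3). Endothelial markers were higher for 6 of 7 (adjusted p = 0.116), with Aqp1 at 0.97 (0.57 without Control 3) and Lyve1 at −0.58. The respiratory chain split evenly, 19 of 38 higher (adjusted p = 0.851, mean −0.15 with no scaling), and the antioxidant and glutathione enzymes were higher for 15 of 27 (adjusted p = 0.851), with Gsta3 at 0.98 (0.37 without Control 2) and Akr7a3 at −0.77. The mean of the last list was 0.01 and turned to −0.15 with no scaling. Immediate early genes gave an adjusted p of 0.725 (median 0.08, mean −0.17), where Dusp1 (−1.32) fell adjusted over the list alone and Egr1 differed by −1.05 (−0.47 without Control 1). The circadian clock (0.921, median −0.01, mean 0.06 and −0.08 with no scaling), cell cycle (0.969), cholangiocyte (0.906), exocrine pancreas (0.642) and erythroid lists (0.921, median 0.08, mean −0.09) were likewise not past the camera threshold. Per2 differed by −0.89, Pcna by 0.29, Krt19 by −0.51, Cela1 by −0.46 and Slc4a1 by −0.57, and without Control 2 Pcna by 0.08, Krt19 by −0.30 and Slc4a1 by −0.32. Without Control 1 Pcna differed by 0.54. At least 1 other probe set had the opposite sign for the list members A2m, Canx, Cdkn1a, Egr1, Got2, Otc, Prlr, Psmd1 and Slc4a1. With an estimated correlation camera called 0 of the 34 lists, with mitochondrial oxidation (0.00385) and lipid uptake (0.0197) at an unadjusted p under 0.05, and fry called 1, mitochondrial oxidation.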

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

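The settings that leave out both Control 2 and NASH 2, or use the arrays with a filled wash record only, were chosen after seeing the data. So was the use of quantile normalization for the tests, which was planned as an alternative and changed places with no scaling. The remaining settings were planned. The count of 7 called probe sets (5 higher, 2 lower) was 6 with array medians set equal (3 and 3), 5 with no offset, 8 with the larger offset and 8 with the stricter filter. It moved to 14 with no scaling between arrays (8 and 6), 0 with no filter (8740 probe sets tested, 630 at an unadjusted p under 0.05), 3 with one prior variance, 18 with array weights (11 and 7), 3 with the wash record as a block and 2 with the mean of a gene's probe sets. It was 16 (13 and 3) without Control 2 and NASH 2, of which 4 were among the 7, and 1 on the filled wash records. At an adjusted p under 0.10 there were 14, and at an unadjusted p under 0.05 with a 2-fold change 127. Leaving out 1 array at a time gave 0 to 17 calls by limma, with 266 to 511 at an unadjusted p under 0.05, and 17 only without NASH 2. With fewer probe sets or arrays the number of tests or of samples differs by construction, and otherwise the cause was not tested. With the replicate number as a block there was 1 call. Nothing in the sources used here states that the numbers pair the samples. Deviations of same-numbered arrays correlated at 0.05, −0.02 and 0.07, and those of other pairs at −0.13 to 0.08. Control 2 correlated best with NASH 1 (0.08), and Control 1 and Control 3 with the NASH array of their own number. Correlations this small cannot decide whether the samples were paired. The count of 13 called lists lay between 9 and 14 under the other settings, except that an estimated correlation gave 0, fry gave 1, and leaving out 1 array at a time gave 8 to 13. Over 714 list results under alternatives, 634 kept their side of the threshold, 67 lost and 13 gained a call, and 70, none called in either fit, had the other direction of the test. Only the 13 called of 34 lists could lose a call. Over 2875 results of 153 named probe sets, 2804 kept their side, 49 lost and 22 gained a call, and 52, none called in either fit, had the other sign. Only the 5 called ones could lose a call, so the 2804 are mostly results never called. Acot2 and Scd were called in 10 of 18 other settings, Eci1 in 7, Igfbp1 in 6, and Cd36 in 5 of 12. The 5 named calls kept their direction in every setting that measured them, with log2 ranges of 2.98 to 3.72 for Acot2, 2.35 to 3.29 for Cd36, 2.38 to 3.14 for Eci1, −4.61 to −3.60 for Scd and −1.89 to −1.59 for Igfbp1. Signal over background limits the called Cd36 probe set, which no fit without a NASH array tested because it lay below the filter, while the other Cd36 probe set was tested in all 6 fits without 1 array (1.36 to 1.88). The 3 against 3 arrays allow 10 splits, too few for a share under 0.05: the real split called 7 probe sets and the highest other 3, and 13 lists against 11. With the preset correlation every other split called at least 2 lists, while fry called 0 in each of them and 1 in the real split.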

Other observations

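The tests of RNA degradation, a wrong label, scaling, the washing run and a shared diet effect were chosen after the result was seen, and the tests on fat, muscle, feeding and PPAR-alpha gene sets were written before their genes were looked at. Genes in this part are otherwise outside the naming rule and were picked after their values were seen.

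NASH 2 differed from the other 5 arrays in genes of tissues other than liver. Besides Fabp4, Ucp1, Acta1 and Ckm, it had the highest deposited signals of the heart and fat binding protein Fabp3 (392 against at most 18.0), the muscle and brown fat subunit Cox8b (353 against at most 22.6), lipoprotein lipase Lpl (345 against at most 40.01), troponin Tnnc2 (196 against at most 17.0) and the muscle calcium pump Atp2a1 (148 against at most 20.5). Slc2a4, S100b and the myosin Myh4 were not highest in NASH 2. Control 3 had 11 probe sets at least 4-fold below the other arrays, and the highest actin 3' to 5' ratio of the 6, 5.07.

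Control 2 combined high signals of genes of amino acid breakdown with low signals of sterol synthesis. Got1 of the amino acid list was at 9.10 on the log2 scale against at most 7.07. Genes outside that list were also high, Hsd17b2 at 9.93 against at most 6.72, Igfbp2 at 6.07 against at most 3.94 and the clock gene Nr1d1 at 5.69 against at most 3.22. Fdps of sterol synthesis was at 6.71 against at least 8.88, and Gpam of the fatty acid synthesis list at 2.43 against at least 4.48. The mean of the urea cycle and amino acid list was 0.64 in Control 2 and between −0.26 and 0.07 in the other arrays.

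The first pattern is the fat transcripts in NASH 2. Of 9 adipose genes not looked at before, 7 were highest in NASH 2, where chance gives 1.5, and of 8 skeletal muscle genes 7 were, where chance gives 1.33. RNA from brown fat and from skeletal muscle in this sample is a candidate explanation, although in the other 5 arrays 1 of the 9 adipose and 4 of the 8 muscle genes also lay above the intensity filter on average, and 3 of the 9 are in the adipose list of the report. An effect of the diet shared by the NASH arrays was tested over 12 fat and muscle markers above the filter in the other arrays. Their difference to the Control mean had a median of 1.97 in NASH 2. The upper quartile was 0.20 in NASH 1 and 0.40 in NASH 3. Of the 12, 7 were adipose genes already looked at, so this gap was partly fixed in advance. Among those not looked at before, Aqp7, Ckm, Myl1 and Casq1 differed by 1.27 to 4.13 in NASH 2, and Myh4 by −0.89. In NASH 1 and NASH 3 these lay between −0.33 and 0.29, which argues against a shared effect as the whole cause for Aqp7, Ckm, Myl1 and Casq1. A response in this sample alone stays open, as does how such RNA reached it.

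The second pattern is Control 2, which differed from Control 1 and Control 3 in sterol, clock and amino acid genes. RNA degradation is argued against by its actin 3' to 5' ratio of 2.15, the lowest of the 6 arrays. A NASH array under a wrong label is argued against by mitochondrial oxidation, the list with the smallest camera p in the fit without Control 2, whose mean in Control 2 was −0.43, against −0.42 and −0.40 in the other Control arrays and 0.28 to 0.50 in NASH, although 3 of the 12 lists called without Control 2, among them fatty acid synthesis (−0.65), lay nearer NASH. The share of probe sets at a limma p under 0.05 without an array in which that array lay nearer Control does not part the groups, at 48.0% for Control 2, 40.9% to 55.9% for the other Control arrays and 27.1% to 50.1% for NASH. Another feeding state or time of sampling may be involved, but 3 of 6 genes not looked at before (Dbp, Taldo1 and Acsl5) were at the predicted extreme, where chance gives 1 and 4 were needed, so it stays open. Dbp is also in the fixed circadian clock list and among the clock genes of this pattern, so it is not independent of it. The count rests on near ties, with Taldo1 at 6.99 in Control 2 and 7.01 in NASH 3, and Wee1 at 4.05 and 4.06.

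The third pattern is the higher level of fatty acid oxidation genes in NASH. Scaling is argued against as the whole cause, since the list mean was at least 0.68 and the list was called in each of the 3 scalings, although the median of all probe sets moved from −0.02 to −0.17 with no scaling. The washing run cannot be told apart from the diet, because the runs of NASH 3 and Control 2 (difference 0.94) were not recorded. Activation of the fatty acid receptor PPAR-alpha may contribute: the median of 6 target genes outside the lists was 0.57, but 4 of 6 were higher where 5 were needed, so this stays a hypothesis. For 7 called probe sets and 13 called lists, the real grouping was the only 1 of 10 with as many calls, which is too few splits for a share under 0.05, and the highest other split gave 3 and 11.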
